A study of Mus musculus with 14 samples.

How the data were processed

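Chromatin from cardiomyocyte-enriched cells of C57BL/6J mice, from sham hearts and from hearts 1 week after transverse aortic constriction, was immunoprecipitated with antibodies against G9a, H3K9me2 and H3K27me3. Per the labels' protocols, libraries were made with the NuGEN Ovation Ultralow V2 kit. The 14 libraries comprise 2 biological replicates of each of the 3 antibodies in each of the 2 conditions, and 1 input per condition. Sex is not given in the labels. Input libraries were not used here, since the tables hold no values for them.

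Per the submitters' processing notes, reads were handled with BWA 0.7.10-r789 and SAMtools 1.1, with the mouse build mm10 (GRCm38). The caller of the differential regions, its input correction and its scaling are not given in the sources used here. The authors deposited 1 table per antibody, without a header. Each line holds the coordinates of a region and, in column 11, 4 whole numbers and a -log10 p; the first 2 numbers were taken as the libraries of one condition and the others as those of the other. Column 6 is + where the first pair is higher and - where the second is, in every line. Whether the authors scaled these deposited values, corrected them for input or summed them over overlapping bins is not stated, so they were not treated as raw read counts. The largest p in the deposited tables was 0.01, the lowest mean value per kb was 105 in each table, and the -log10 p is the authors'. No table says which pair is sham, nor which replicate stands where. Directions are therefore given by pair, and if the pairs follow the other order, each statement about the conditions turns round; no statement here depends on it.

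The tables held 1186058 regions, 1186054 of them on chromosomes 1 to 19, X and Y and 4 on mitochondrial DNA, which stayed out of all comparisons. The log2 difference of a region is that of the pair means, second over first, with a pseudocount of 1. It understates the change of low regions, and where a pair was listed at 0 no fold is given. A region counts as separated when both values of its higher pair exceed both values of the other. No chance rate is given for this, since the regions were selected for a difference between the pairs. With 2 libraries per pair, an exact permutation test of a single region cannot go below p = 0.333, two-sided. A difference was therefore called by the authors' deposited p, and limma 3.58.1 (R 4.3.3) on log2(value + 1) of all regions, without further scaling, gave a second look at regions that the authors had already selected. A count model had been foreseen for raw counts and was not used.

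Genes came from the gene table of assembly GRCm38.p6, with 21887 protein-coding genes on these chromosomes. It gives gene starts and ends without strand or exons. Windows of 2500 bp either side of transcription start sites had been foreseen; windows of that size around both annotated ends of each gene were used instead, with the rest of the gene body as a second class, and exons and introns were not told apart. Shares of region midpoints are given with 95% intervals from 1000 resamples of whole chromosomes. Of each of 20 gene lists, the number of genes with a region in either direction was compared with all other genes by Fisher's exact test, two-sided, and the 120 tests were adjusted together by the Benjamini-Hochberg method. At an adjusted p of 0.05, 48 passed. Adjusted over the list alone, with 6 tests each, 51 passed. Neighbouring genes, such as Hox genes and receptor clusters, share regions, so these p-values are too small. Genes with more signal can have a listed region more readily, so these tests do not tell a larger change from more signal. The windows around both ends of a short gene overlap, as at many olfactory receptor genes. Less sequence was therefore searched there than at long genes. Lists covered fetal and stress genes, the sarcomere, calcium handling and ion channels, cardiac transcription factors, growth signalling, immediate early genes, fatty acid oxidation, glycolysis, autophagy, extracellular matrix, H3K9 and H3K27 methylation enzymes and readers, Hox genes, developmental regulators of other lineages, neuronal genes, olfactory and vomeronasal receptors, and markers of fibroblasts, endothelium, smooth muscle with pericytes, and leukocytes. All their symbols were matched.

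Overlap between tables was counted from 1 bp on a 50 bp grid and compared with 1000 circular shifts within each chromosome, with a two-sided p adjusted over the 12 pairs of lists. The list tests take genes and the shifts take regions as their units. With 2 libraries per pair, their p-values do not measure the spread between animals. The lists, tests, thresholds and the rule for named genes were set before the data were examined. Named genes are the 8 per table and direction with the smallest deposited p in a window shared with at most 3 other genes, up to 4 members of each list that passed, 11 cardiac and chromatin genes, and the 10 genes ranked by the weakest of the tables that share them. The value of 1 list member is not reported here. The region near Arid1b and the mitochondrial regions lie outside this rule and were chosen after their values were seen.

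The list test was tested on simulated data for H3K27me3 regions higher in the second pair, over 21887 genes. It called 3% of 1000 unchanged lists and 100% of changed ones. The shifts called 0% of 20 unchanged and 100% of changed simulations for G9a on H3K27me3 on chromosome 1, with 12381 regions. The changed lists had hits at most of their genes, and the changed overlaps a mean fold of 1.47. Hits were drawn gene by gene and unchanged regions placed at random, whereas the real genes and regions lie in clusters. These simulations therefore do not measure false calls under clustering. Among 200 regions changed by 4 times, limma called 60 for G9a, 85 for H3K9me2 and 104 for H3K27me3. All simulated regions of a table were given the same spread, the median of the first pair. Real regions differ in spread, so these numbers do not measure how many real changes limma would find. Alternatives set beforehand were a p 10 times smaller, a difference of at least 2 times, merging within 1000 bp, each library left out, windows of 1000 and 5000 bp, shares by base pairs, overlap of at least 0.5 of the shorter region, shifts of at most 1 Mb, scaling by the trimmed mean of M values, and a filter on a mean value of 10. Added after seeing the data were separated regions, equal medians, gene bodies against 1000 lists matched on gene length, exclusion of X and Y, limma without each library, the G9a lists and overlaps without library 1 of the second pair, and rankings and the zinc finger cluster without each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.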

Results

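The series profiled cardiomyocyte-enriched cells of C57BL/6J mice by chromatin immunoprecipitation and sequencing, 1 week after transverse aortic constriction, a surgical narrowing of the aorta that puts the left heart under pressure load, and after a sham operation. Antibodies recognised G9a, the histone methyltransferase encoded by Ehmt2, its repressive product H3K9me2, and H3K27me3, the repressive mark placed by Polycomb complexes. There were 14 libraries: 12 immunoprecipitated ones, with 2 biological replicates per antibody and condition, and 2 input libraries, 1 per condition. The question was where in the genome the enzyme and the marks differ between loaded and sham hearts. For each antibody, the authors' deposited table lists genomic regions that differ between the conditions, with 4 whole-number values per region: a first pair of libraries and a second pair. All log2 values below given for the authors' deposited tables were computed here from the pair means, second over first, as the tables hold none. The tables do not name the pairs. Their titles mention sham before constriction, but whether the values follow that order is not given in the sources used here, so differences are given as higher in the first or the second pair, and the same order was assumed in the 3 tables.

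The authors' deposited tables held 1186054 regions on nuclear chromosomes: 388424 for G9a, 245088 for H3K9me2 and 552542 for H3K27me3. Values summed over the listed regions ran from 36881071 to 48327896 per library for G9a, from 22175663 to 23973355 for H3K9me2 and from 112764904 to 143213031 for H3K27me3. These sums cover listed regions only and are not sequencing depths, which are not given in the sources used here. Among the G9a libraries, library 1 of the second pair stood apart: 9.34% of its values were 0, against 0.163% to 1.40% in the other 3, and its median value was 52, against 77, 94 and 90.

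For G9a, the second-pair regions with the smallest p in the authors' deposited table, among regions near the ends of at most 4 genes, lay at Kif26a, a kinesin family gene (chromosome 12, 112173051 to 112181500, mm10), and at Ldc1. Kif26a had values of 953 and 867 in the first pair and 4958 and 2281 in the second in the authors' deposited table, a log2 difference of 1.99, and Ldc1 1250 and 2069 against 9217 and 3801 (1.97). The region shared by C1qa, C1qb and C1qc, which encode the subunits of complement C1q, was higher by a log2 value of 1.45 in the authors' deposited table. Those at Cpne5, Elfn1 and Agxt, a glyoxylate-detoxifying aminotransferase, were higher by 1.75, 1.70 and 1.59 in the authors' deposited table. Near gene ends, regions higher in the first pair were led by zinc finger genes on chromosome 4. Log2 values computed from the authors' deposited table were -1.27 at Zfp993 (1925 and 2759 against 455 and 1488), -1.40 at Zfp992, -1.21 at Zfp982, -1.25 at Zfp981 and -0.68 at Zfp978, where the 4 values of the pairs overlapped. Mucl2 had -1.60, and the window shared by Osbpl7 and Mrpl10, a mitochondrial ribosomal protein gene, had 282 and 314 against 2 and 29 in the authors' deposited table.

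G9a regions higher in the second pair lay within 2500 bp of an end of all 39 Hox genes, the body-plan regulators (42.4% of other protein-coding genes; adjusted p = 3.42e-14, Fisher's exact test), and of 56 of 61 developmental regulators of other lineages (7.02e-15). Examples in the authors' deposited table were Lhx2, 199 and 410 against 1083 and 733, Neurog3, 169 and 250 against 589 and 875, and Hoxb3, 22 and 249 against 276 and 584. Many of these genes also had a region that was higher in the first pair: 37 of 39 Hox genes (4.38e-06) and 48 of 61 developmental regulators (0.00631). Around Hox genes 44 of 159 G9a regions had both values of the higher pair above both of the other, against 61.3% of all G9a regions. Neuronal genes had a second-pair region at 19 of 26 (0.00879), among them Grin1, a glutamate receptor subunit, with a log2 value of 1.29 in the authors' deposited table.

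Markers of other heart cell types were also near G9a regions higher in the second pair. By Fisher's exact test these were 13 of 15 endothelial markers (adjusted p = 0.00350), 9 of 10 smooth muscle and pericyte markers (0.00952) and 12 of 15 leukocyte markers (0.0187). They also included 11 of 14 fibroblast markers (0.0319) and 18 of 27 extracellular matrix genes (0.0461). In the authors' deposited table, log2 values were 1.39 at Pdgfrb, 1.40 at Erg, 2.11 at Thy1 and 1.72 at Mmp2, a gelatinase. Second-pair G9a regions were fewer than elsewhere at glycolysis genes (2 of 20, Hk1 and Ldha; 0.00952) and at H3K9 and H3K27 methylation enzymes and readers (6 of 34; 0.00952). They were also fewer at olfactory receptors (225 of 1110; 5.11e-56) and at vomeronasal receptors (49 of 355; 1.57e-30). First-pair regions were fewer at olfactory (575 of 1110, 4.38e-06) and vomeronasal receptors (153 of 355, 1.01e-08). The vomeronasal first-pair result held with separated regions alone (3.46e-04, Fisher's exact test), while the olfactory one did not (0.597). In gene bodies against lists matched on gene length the olfactory first-pair result reversed (298 genes against 233). With the direction taken without library 1 of the second pair, the matrix genes (0.160) and the fibroblast markers (0.0704) no longer passed the threshold. With separated regions alone, the second-pair results of endothelial (0.0633), smooth muscle and pericyte (0.175), fibroblast (0.271) and glycolysis genes (0.183) did not pass. Those of leukocyte markers (0.0134), matrix genes (0.0095), methylation enzymes and readers (0.001135) and both receptor families did.

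For H3K9me2, the second-pair region near a gene end with the smallest p in the authors' deposited table lay at Dnmt3b, a de novo DNA methyltransferase (chromosome 2, 153646751 to 153649950), with 259 and 482 in the first pair and 2707 and 2553 in the second, a log2 value of 2.82. Adrb1, the main beta-adrenergic receptor of the heart (chromosome 19, 56722251 to 56724050), had 45 and 123 against 1747 and 650 (3.82) in the authors' deposited table. Ankrd1, a stress-responsive sarcomere gene, had 135 and 76 against 941 and 919 (3.13) in the authors' deposited table. Log2 values there were 2.19 at Prdm16, 1.99 at Wls, a Wnt secretion factor, 1.57 at Laptm5, 1.44 at Crlf2 and 1.42 at Ldc1. Regions higher in the first pair again included the zinc finger genes, with log2 values in the authors' deposited table of -1.12 at Zfp982 and -0.86 at Zfp992. Zfp981 was listed at 0 and 0 in the second pair against 332 and 275, and Zfp978 at 0 and 2 against 295 and 291. H2-Q7, a class I histocompatibility gene, had 310 and 425 against 13 and 19 in the authors' deposited table. The window of Doc2a and Ino80e had 221 and 429 against 0 and 48 there, and Gm5373 a log2 value of -0.82.

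H3K9me2 regions of both directions were frequent at chemosensory receptor genes, which stand in large clusters. Olfactory receptors had a second-pair region at 483 of 1110 genes (17.9% of other genes; Fisher's exact test, adjusted p = 3.80e-79) and a first-pair region at 479 (1.55e-35). Vomeronasal receptors had them at 135 (1.55e-15) and 158 (3.91e-13) of 355. First-pair H3K9me2 regions were fewer at glycolysis genes (0 of 20; 0.0122), at autophagy genes (1 of 34, Atg5; 0.00296) and at methylation enzymes and readers (3 of 34, Kdm4c, Mtf2 and Ehmt1; 0.0471). None of the other gene lists passed the threshold for H3K9me2 in either direction.

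For H3K27me3, second-pair regions reached all 39 Hox genes (46.4% of other genes; Fisher's exact test, adjusted p = 9.69e-13, and 3.15e-13 adjusted over the list alone), 60 of 61 developmental regulators (6.92e-18) and 26 of 26 neuronal genes (1.80e-08). The region over Hoxc8, Hoxc9 and Hoxc10 had values of 14269 and 14587 in the first pair and 25690 and 24174 in the second in the authors' deposited table, a log2 value of 0.79. Neurog1, En1, Pax2 and Olig2, regulators of neural and kidney development, had log2 values of 0.80, 0.70, 0.69 and 0.62 there. The neuronal genes Rbfox3, Nefl, Grin2a and Csmd1 had 0.78, 0.69, 0.68 and 0.80 in the authors' deposited table. First-pair regions were fewer at Hox genes (6 of 39; 3.65e-04) and more frequent at neuronal genes (19 of 26; 0.0266).

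Sarcomere genes were mostly outside the H3K27me3 regions. Of 22 such genes, 0 had a second-pair region (7.24e-06) and 1, Nebl, had a first-pair region (1.10e-04). Second-pair regions were also fewer at fatty acid oxidation genes (3 of 25; 0.00196), autophagy genes (5 of 34; 9.68e-04), growth signalling genes (5 of 29; 0.00537) and calcium handling and ion channel genes (6 of 29; 0.0156). First-pair regions were fewer at fatty acid oxidation (3 of 25; 0.00195), autophagy (6 of 34; 0.00215), glycolysis (3 of 20; 0.0165) and immediate early genes (3 of 20; 0.0165). They were near 11 of 29 calcium handling and ion channel genes and 11 of 29 growth signalling genes, which did not pass the threshold (0.505 each, Fisher's exact test). Members with a second-pair region in the authors' deposited table included Ppargc1a, a coactivator of mitochondrial genes, with 339 and 293 against 1161 and 693 (log2 1.55). Others in the authors' deposited table were Rxra with 0.87, Kcna5 with 0.79, and Sln, which encodes the calcium pump inhibitor sarcolipin, with 0.65.

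Markers of other cell types were near H3K27me3 regions higher in the second pair at 15 of 15 endothelial (6.17e-05), 13 of 15 leukocyte (0.00952) and 12 of 14 fibroblast genes (0.0157), and at 19 of 27 matrix genes (0.0471). First-pair regions were near 12 of 15 endothelial (0.0446) and 13 of 15 leukocyte markers (0.00952), so most of these genes carried both. Sox18, Cdh5 and Vwf of the endothelium had log2 values of 0.91, 0.88 and 1.02 in their second-pair regions in the authors' deposited table, while Kdr had -1.26 in its first-pair region. Olfactory receptors had first-pair regions at 756 of 1110 genes (1.90e-46) and second-pair regions at 382 (8.30e-16, fewer than other genes). Vomeronasal receptors had them at 208 (6.17e-05) and 85 (1.68e-17) of 355. In gene bodies against lists matched on gene length, second-pair regions at olfactory receptors no longer passed as fewer (257 genes against 277, adjusted p = 0.1165, permutation of matched lists).

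Of the H3K27me3 regions, 75 were tied at a p of 0 in the authors' deposited table, among them those of Hoxc8 to Hoxc10, Neurog1, En1, Pax2 and Olig2. Of the tied second-pair regions near the ends of at most 4 genes, those with the largest log2 values in the authors' deposited table were at Cacng2 (3892 and 3900 against 9309 and 8038; log2 1.15), Col5a3 with Rdh8 (0.96), the keratin genes Krt82, Krt90 and Krt75 (0.96) and Wnt9b with Wnt3 (0.94). Near gene ends, the first-pair regions with the smallest p in the authors' deposited table were at Zfp992 (3437 and 2823 against 1807 and 1063; -1.13), Crisp4 (-1.34) and Exosc4, an RNA exosome subunit gene (491 and 376 against 49 and 36; -3.32). Efhb (-2.46), Trim47 (-1.55), Zfp788 (-3.93), Tbc1d31 (-4.21) and Defa30 (-3.42) followed in the authors' deposited table.

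**Figure D1:**
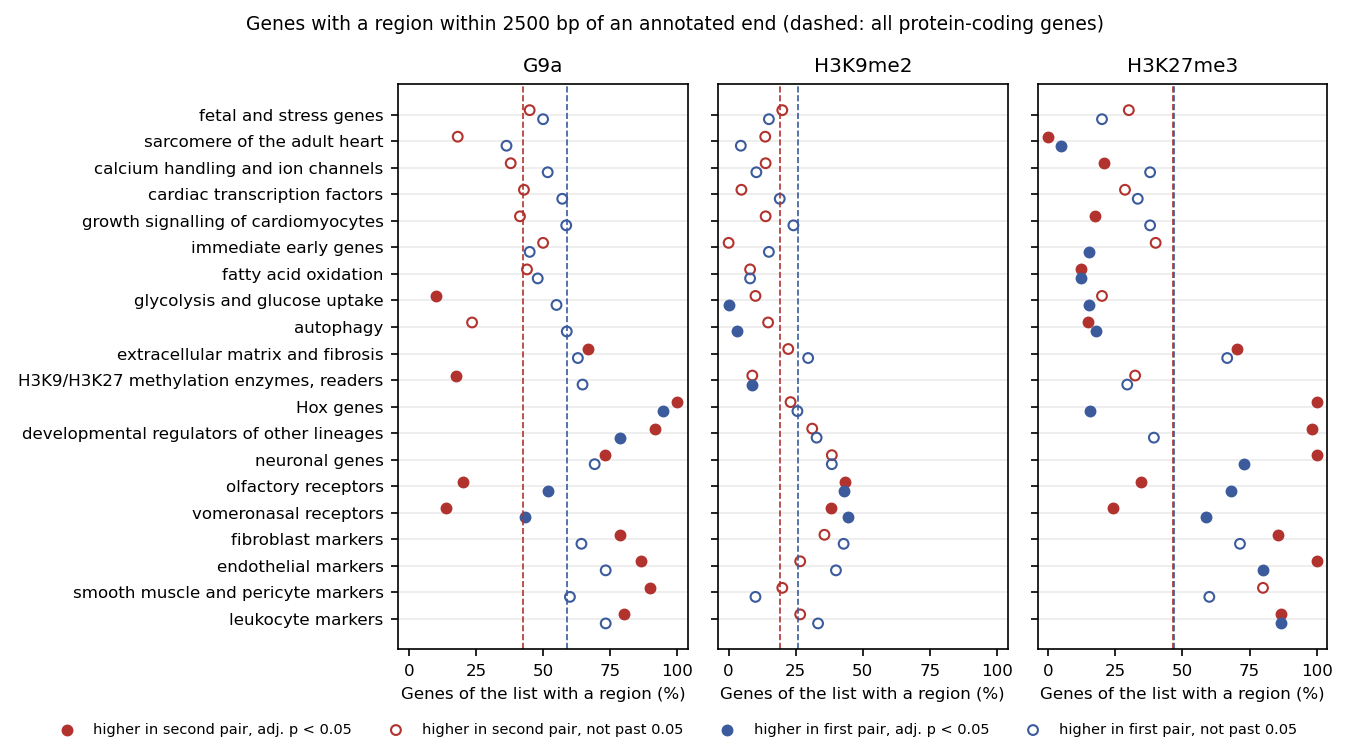
Share of each gene list, in percent, with a region within 2500 bp of an annotated gene end, for G9a, H3K9me2 and H3K27me3 (red, higher in the second pair; blue, higher in the first pair; filled, adjusted p under 0.05; dashed lines, all protein-coding genes). Hox genes reach 100% in red for G9a and H3K27me3, and sarcomere genes 0% in red for H3K27me3.

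The fetal and stress genes of the hypertrophic heart and the cardiac transcription factors did not pass the threshold for any antibody or direction. The former had second-pair regions at 9 of 20 genes for G9a (Fisher's exact test, adjusted p = 0.917), 4 for H3K9me2 (1) and 6 for H3K27me3 (0.311), and the latter at 9 (1), 1 (0.289) and 6 (0.232) of 21. Nppa and Nppb, the natriuretic peptide genes induced by load, had a region in the H3K9me2 table alone, higher in the second pair. Its values in the authors' deposited table were 30 and 109 against 180 and 150 for Nppa (log2 1.24) and 138 and 71 against 177 and 170 for Nppb (0.73). Myh6, Myh7, Mef2c and Gata4 had no region within 2500 bp of an end in any of the 3 tables. Acta1, the skeletal actin gene, had neighbouring regions of opposite direction in the authors' deposited tables for G9a (1.09 and -1.54) and H3K27me3 (1.37 and -0.77), given for the smallest p per direction. For G9a, Acta1 had 2 regions of each direction near its ends. For H3K27me3, Acta1 had 6 higher in the second pair and 1 higher in the first. Its H3K9me2 region was higher in the first pair (45 and 119 against 5 and 58, log2 -1.35), with overlapping values of the pairs. Atp2a2, the calcium pump gene, had -1.41 and Ezh2, an H3K27 methyltransferase gene, -0.89 for G9a in the authors' deposited table. At 1 end of Ehmt2, also near an end of a neighbouring gene, a region was higher in the second pair in the authors' deposited tables. This held for G9a (227 and 458 against 1138 and 695, log2 1.42) and H3K9me2 (187 and 390 against 1003 and 877, log2 1.70). Strand was not given, so whether this end is the start of Ehmt2 was not told. For H3K27me3 Ehmt2 had neighbouring regions of opposite direction in the authors' deposited table (0.71 and -1.17).

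Of the 48 list results past the threshold, 23 held in every alternative tried. For G9a these were the second-pair results of Hox, developmental and neuronal genes, of methylation enzymes and readers and of both receptor families, and the first-pair result of vomeronasal receptors. For H3K9me2 they were the results of both receptor families. For H3K27me3 they were the second-pair results of Hox, developmental, neuronal, endothelial, sarcomere, fatty acid oxidation, autophagy and vomeronasal receptor genes, and the first-pair results of sarcomere, autophagy, olfactory and vomeronasal receptor genes. The other lists lost the threshold in at least 1 alternative, and the G9a first-pair result of olfactory receptors reversed with gene bodies in place of gene ends (adjusted p = 0.00705, permutation of matched lists). Of single libraries, only library 1 of the second pair was left out of these tests, and for G9a alone. Near Hox genes G9a values summed to 16044 and 30163 in the first pair and 15833 and 42610 in the second. Near developmental regulators the sums were 26587 and 48207 against 36118 and 72888. Both second-pair results thus lean on library 2 of that pair, which was not left out.

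Of the G9a regions higher in the second pair, 52.3% overlapped an H3K27me3 region of the same direction, 2.54 times the mean of 1000 circular shifts, with 77.2 Mb shared. With shifts of at most 1 Mb this fold was 1.81, below the 1.94 of G9a on H3K9me2 regions higher in the second pair. The permutation p from these shifts was 0.00200 after adjustment, the smallest they can give, as for all 12 pairs of lists. The shifts run over all sequence between the outermost regions of a chromosome, also where no region could be listed. A fold above 1 can therefore come from tables that hold regions in the same parts of the genome, and this p does not show a shared change. The opposite combinations gave 1.13 and 1.26 times, and regions higher in the first pair for both antibodies gave 1.46 times. Folds of the same direction were 1.60 and 1.78 for G9a on H3K9me2, against 1.21 and 1.43 for opposite directions. For H3K9me2 on H3K27me3 they were 1.51 and 1.79, against 1.502 and 1.24. Same-direction base pairs made up 58.9%, 70.0% and 57.7% of those shared by G9a and H3K9me2, G9a and H3K27me3, and H3K9me2 and H3K27me3. At stricter p, the overlap of G9a regions higher in the second pair with H3K27me3 regions higher in the first fell to 1.02 times and no longer passed the test.

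**Figure D2:**
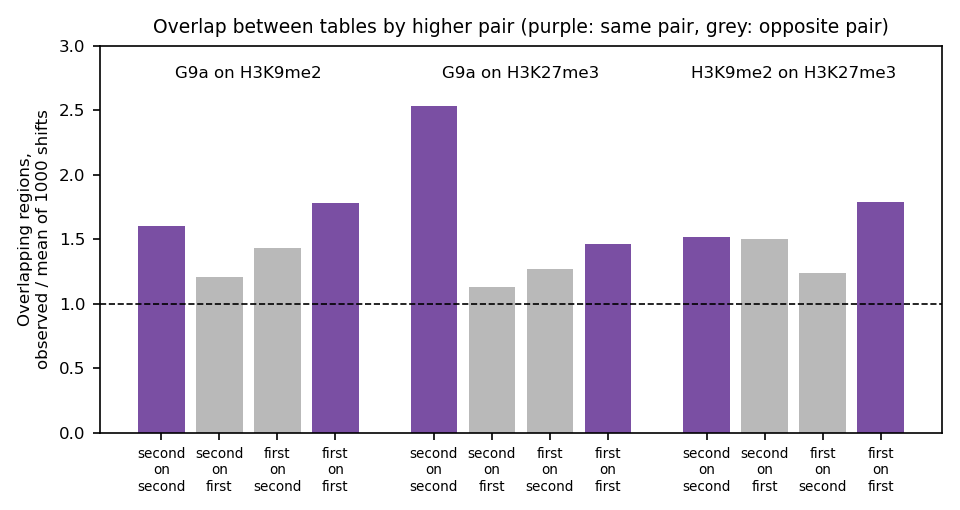
Number of regions of one table that overlap another table's regions, as a ratio to the mean of 1000 circular shifts, for each combination of directions (purple, same pair higher in both; grey, opposite pairs; dashed line, 1). The bar of G9a on H3K27me3, second pair higher in both, stands highest at 2.54.

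With regions near the ends of more than 4 genes left out, 5527 genes had a region near an end in all 3 tables. Those with the strongest weakest mark were Ldc1, Zfp992, Laptm5, Zfp981, Odf3l2, Zfp978, Lad1, Zfp988, Tmem267 and Zfp982. Lad1, which encodes ladinin, was higher in the second pair in the authors' deposited tables for G9a (39 and 77 against 766 and 191; log2 3.02), H3K9me2 (2.26) and H3K27me3 (1.13). Odf3l2 had 1.59, 1.72 and 0.53 there, and also an H3K27me3 region of -0.72. With the same regions left out, G9a and H3K9me2 were both higher in the second pair at 2093 genes. The strongest of these were Ldc1, Dnmt3b, Adrb1, Ankrd1, Crlf2, Tcstv3, Laptm5, Ehmt2 with its neighbour Slc44a4, and Wls. With no region left out, second-pair regions were near 9307 genes (42.5%) for G9a and 4202 (19.2%) for H3K9me2, of 21887. Neither the 2093 nor the 5527 genes were set against the number that unrelated tables would share. G9a log2 values in the authors' deposited table were 1.86 at Dnmt3b (399 and 615 against 2797 and 901), 1.75 at Adrb1, 2.56 at Ankrd1 and 2.33 at Tcstv3.

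By number, regions higher in the first pair were the majority in each authors' deposited table: 215389 of 388424 for G9a, 136371 of 245088 for H3K9me2 and 316648 of 552542 for H3K27me3. For G9a and H3K27me3 the majority depends on the authors' deposited p, while for H3K9me2 it stayed with the first pair. At a -log10 p of at least 10, 55.7% of G9a, 45.1% of H3K9me2 and 47.4% of H3K27me3 regions were higher in the second pair. At 20 or more these shares were 70.6%, 47.8% and 57.5%. Regions higher in the second pair were longer for G9a (median 700 against 550 bp), H3K9me2 (650 against 600 bp) and H3K27me3 (900 against 750 bp). They covered more sequence for G9a and H3K27me3, 159 against 135.0 Mb and 327 against 265 Mb, while H3K9me2 covered 75.7 against 88.8 Mb. Of the G9a regions, 9.0% of those higher in the second pair had their midpoint within 2500 bp of a gene end (95% interval over chromosomes 7.99% to 9.99%) and 7.4% of those higher in the first. For H3K27me3 these were 7.3% and 4.4%, for H3K9me2 4.2% and 4.4%, and the windows take up 6.8% of the span. Among the 10% of regions with the highest values per kb, 77.6% of G9a, 64.2% of H3K9me2 and 70.7% of H3K27me3 regions were higher in the second pair, against 25.8%, 30.7% and 21.8% among the 10% with the lowest. This order turned when a library of the second pair was left out of ranking and direction. Without its library 1 the highest 10% gave 37.2%, 31.9% and 54.5%, and the lowest 10% gave 88.3%, 82.4% and 74.9%. Without its library 2 these were 54.6%, 31.2% and 61.1% against 64.0%, 80.1% and 84.3%. Without library 1 or 2 of the first pair they gave 89.2% and 89.5% (G9a), 83.0% and 84.9% (H3K9me2) and 80.5% and 77.4% (H3K27me3). Leaving out a library weights such a ranking towards the other pair, so the turn does not show that the order rests on that library. Ranked by length instead, the longest 10% were higher in the second pair for 80.4% of G9a, 52.2% of H3K9me2 and 80.1% of H3K27me3 regions.

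**Figure D3:**
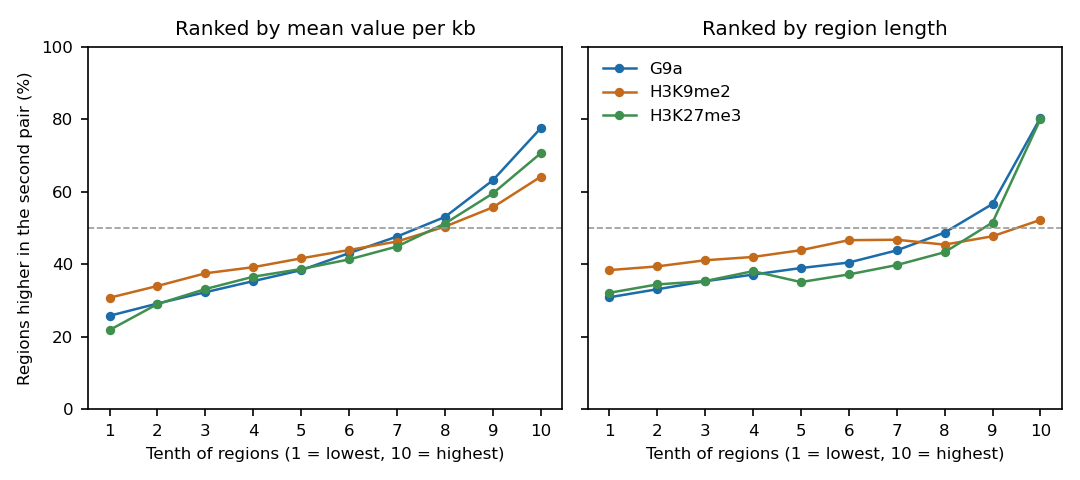
Share of regions higher in the second pair, in percent, in 10 equal parts of each table ranked by mean value per kb (left) or by length (right); the dashed line marks equal numbers of both directions. G9a rises from 25.8% to 77.6% on the left and from 30.9% to 80.4% on the right. The left-hand course turns when a library of the second pair is left out of the ranking and the direction, which weights the ranking towards the first pair.

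Without further scaling, few regions passed a test across libraries. The p-values of the list tests and shifts above do not measure the spread between libraries. By limma on log2(value + 1), 0 G9a regions and 0 H3K27me3 regions passed an adjusted p of 0.05, and 1 H3K9me2 region did. It lay on chromosome 17 (4625651 to 4627250), 367046 bp from the nearest gene, Arid1b. Its values were 757 and 670 against 5655 and 10041 in the authors' deposited table (log2 3.402, limma adjusted p = 0.0440). It did not pass when any 1 library was left out. At an unadjusted p under 0.05 limma counted 26030 G9a regions (6.70%), 28940 H3K9me2 regions (11.8%) and 103684 H3K27me3 regions (18.8%). After scaling by the trimmed mean of M values 9474 H3K27me3 regions passed as higher in the second pair and 259 as higher in the first. The scaling factors came from the listed regions alone, which were selected for a difference, and dividing by them raised the second pair. These 2 counts therefore depend on a scaling that the listed regions cannot settle. Both values of the higher pair exceeded both of the other in 61.3% of G9a, 67.9% of H3K9me2 and 69.2% of H3K27me3 regions, which the authors had selected for a difference.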

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

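Of the tests below, the share at zinc finger genes elsewhere was set before its result was seen. The ranking by the other antibody was set before its own result, but after the ranking by the same values without a library had been seen. The tests of the cell mix, of enrichment, of the X chromosome and of the chromosome 4 cluster were chosen after their results were seen. So were the rankings and cluster ratios without a library.

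Mitochondrial DNA carries no histones and lies outside all comparisons above, yet 4 regions on it were listed. For H3K9me2 the region from 51 to 6600 had 9507 and 5239 in the first pair and 24279 and 18071 in the second in the authors' deposited table, a ratio of 2.87, and the region from 10901 to 15550 a ratio of 2.24. For H3K27me3 the region from 11001 to 16250 had a ratio of 5.64, and the region from 201 to 6550 was listed at 0 and 0 in the first pair and at 14959 and 8621 in the second.

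In the G9a and H3K27me3 tables, regions with the highest values per kb were mostly higher in the second pair. A ranking by the mean of the same 4 values was weighed first: with each library left out of ranking and direction, the G9a share of 77.6% ran from 37.2% to 89.5% and that of H3K27me3 from 54.5% to 80.5%, and without either second-pair library it fell below that of the lowest 10%. Leaving out a library weights such a ranking towards the other pair. A ranking by the other antibody's value in overlapping regions was therefore also used, chosen after the turn without a library was seen. With it the share still differed by at least 32.5 percentage points between the highest and lowest 10% (34.4% to 75.1% for G9a, 39.5% to 72.1% for H3K27me3). Of the base pairs shared by G9a and H3K27me3 regions, 70.0% had the same direction, so this ranking is not independent of the directions. It therefore cannot decide whether ranking by the mean of the same 4 values is the cause, which stays open. Using the other antibody's ranking without each library (66.2% to 78.2% and 70.4% to 73.7%) was chosen after its first result was seen. A different mix of cell types stays open: the lower quartile of the H3K27me3 log2 values near developmental genes was 0.38, but only regions selected for a difference are listed, so unmoved ones cannot appear, and that all heart cell types keep these genes silent was assumed. Stronger enrichment over background in the second-pair libraries stays open, since the median near Hox genes was 0.58 in regions selected for a difference, while mitochondrial values did not fall; a change with constriction stays open too, and these cannot be told apart, as the pairs are the conditions.

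The X chromosome held 0.207% of G9a, 0.479% of H3K9me2 and 0.912% of H3K27me3 regions, against 6.30% of the span. A single X copy set against the lowest value of 105 per kb may leave few X regions; the density on X was therefore set over the share of autosomal regions at or above 210 per kb. As first set, a ratio beyond 2 in any table was to count against this, but more X regions than a single copy leaves do not call for another cause of their shortage; this change, the split by table and the counting intervals came after the values were seen. The ratio was 0.686 for H3K27me3, within the bound, while 7.84 (95% interval 7.30 to 8.41) for H3K9me2 and 2.06 (1.91 to 2.22) for G9a leave a single copy open. Sex is not in the labels, so a biological difference was not tested.

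A cluster of zinc finger genes on chromosome 4 (146449030 to 147516064) was bounded by its Zfp genes among the 8 named per table as higher in the first pair. A lean to the first pair was therefore built in, and the values below describe the cluster without testing it. The cluster was mostly lower in the second pair in all 3 tables, for G9a largely through library 1 of that pair. Of its regions, 77.1% for G9a, 83.7% for H3K9me2 and 77.0% for H3K27me3 were higher in the first pair. The log2 ratios of values summed over the listed regions were -0.69, -0.91 and -0.57 (-0.63, -0.73 and -0.39 after scaling by the trimmed mean of M values). With each library left out they ran from -1.58 to -0.15, -1.03 to -0.77 and -0.85 to -0.33; G9a gave -0.15 and 62.1% without library 1 of the second pair, and 90 of its 214 regions were separated. A difference in DNA copy number or mappability between the animals would shift the 3 tables alike; the ratios spanned 0.34, but they cover listed regions only, selected for a difference in each table apart, so this span decides nothing. A change shared by zinc finger genes elsewhere was also open: 59.5% of H3K9me2 regions near them were higher in the first pair, against 55.6% of all. A copy number difference between mice could be tested from the input libraries, which were not used here, and a change with constriction remains possible.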

How the results depend on the processing

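Separated regions, equal medians, gene bodies, exclusion of X and Y, limma without a library, the G9a results without library 1 of the second pair and the rankings and the zinc finger cluster without a library were chosen after seeing the data; the cause of a change was not tested unless given. Counts of regions kept to within 1.5 times under 50 of 60 alternatives. A difference of at least 2 times left 89073 G9a regions higher in the second pair and 125315 in the first, 50943 and 70913 for H3K9me2, and 76737 and 154943 for H3K27me3, by construction fewer. Separated regions alone were 109137 and 128776 for G9a and 72053 for H3K9me2 in the second pair, and merging within 1 kb left 152429 H3K27me3 regions of the second pair. Without each library, directions gave 156875 to 186823 G9a, 105038 to 112425 H3K9me2 and 225421 to 258827 H3K27me3 regions higher in the second pair.

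Genes near a first-pair region numbered 7978 for G9a, 2956 for H3K9me2 and 6403 for H3K27me3 with windows of 1000 bp, 8332 for G9a with separated regions, and 8996 for H3K9me2 with 5000 bp. Genes near a second-pair H3K9me2 region numbered 2344 with 1000 bp and 6621 with 5000 bp. By base pairs, 32.0% of G9a sequence higher in the second pair lay in gene bodies and 58.3% outside genes, and H3K27me3 gave 9.90% near gene ends, 32.2% in bodies and 57.9% outside. Of 304 alternatives of the 48 list results, 247 kept direction and side of the threshold, 56 lost the threshold and 1 reversed: first-pair G9a regions were more frequent at olfactory receptors in gene bodies (298 genes against 233 in matched lists, adjusted p = 0.00705, against 7.75e-12 to 0.597 with the other alternatives). In every alternative, 23 of the 48 held.

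Overlap folds kept their side in 66 of 68 alternatives; G9a regions of the second pair on H3K27me3 regions of the first gave 1.02 at stricter p and 0.99 for separated regions. With scaling by the trimmed mean of M values, limma called 2 H3K9me2 regions of the second pair, 9474 H3K27me3 regions of the second and 259 of the first; without any library it called 0 for H3K9me2, with fewer libraries, and the lone library was assumed to vary like the other pair. The filter on a mean of 10 removed no region, so it tests nothing. The share of the highest 10% higher in the second pair ran from 37.2% to 89.5% for G9a, 31.2% to 84.9% for H3K9me2 and 54.5% to 80.5% for H3K27me3. It fell below 50% for G9a without library 1 of the second pair (37.2%) and for H3K9me2 without its library 1 (31.9%) or 2 (31.2%). Leaving out a library weights this ranking towards the other pair, so these ranges do not show a dependence on single libraries. The log2 factors of that scaling were -0.12, -0.18 and -0.19 in the second pair relative to the first, and the log2 medians -0.31, -0.18 and -0.29. Dividing by either raises the second pair. Both were taken from the listed regions alone, selected for a difference, so they do not give library sizes.

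No paired analysis was possible because the tables carry no replicate numbers. The alternatives with a count model and with lists matched on GC content were not run, as the values are not raw counts and no sequence was used here. Depth per library is not given in the sources used here, so its limit on low regions is unknown.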

Other observations

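The test in the second paragraph was chosen after overlaps of the strongest regions had been seen.

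Zinc finger genes outside the chromosome 4 cluster, 393 in number, had 542 G9a regions near their ends, of which 67.7% were higher in the first pair, against 55.5% of all G9a regions. For H3K27me3 the share was 53.1%, against 57.3% of all. These differences between the tables were not tested.

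H3K9me2 regions higher in the second pair, such as those at Dnmt3b, Adrb1 and Ankrd1, may reflect G9a and H3K9me2 rising at the same places. Of the 500 H3K9me2 regions with the smallest deposited p in the second pair, 206 overlapped a G9a region of the same direction and 130 one of the opposite direction, a ratio of 1.58. For the first pair these were 189 and 90, a ratio of 2.10. H3K27me3 regions gave ratios of 1.57 (221 and 141) and 1.89 (247 and 131). These were not set against shifts, so whether the coincidence is particular to G9a was not tested. After 1000 circular shifts of the H3K9me2 regions, added later, the ratios for G9a were 0.849 and 1.14, so the observed ones were 1.87 and 1.84 times those without a relation. The lower observed ratio lies between the bounds set for and against the hypothesis, which stays open.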
